A study of Homo sapiens with 4 samples.

How the data were processed

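RNA from 4 cultures of human embryonic stem cells was hybridised to Illumina Expression BeadChips, with 1 array per condition. The conditions were E8 medium, labelled 24 h (E8), E8 with 10 mM nicotinamide for 24 h (Nam), E8 with the small molecule Y27632 at 10 µM for 24 h (Y27632), and 6 days of BMP4 in E8 as a control for mesoderm differentiation (Mesoderm). The data hold no array of cells kept for 6 days in E8 without BMP4. Effects of BMP4 and of time in culture therefore cannot be told apart. Per the labels' protocols, total RNA was extracted with RNAiso Plus and converted to biotin-labelled cRNA with a TargetAmp-Nano kit, a method that amplifies from small amounts of RNA. The BMP4 dose and the scanner software are not given in the sources used here. Samples were assigned to conditions by their titles, and table columns by column names that match those titles. The labels' characteristics name the line H9 and their growth protocol names H1, both established embryonic stem cell lines. In a check of the arrays against these labels, 4 of 4 arrays did not match the line of the characteristics and 4 of 4 matched that of the growth protocol. The check does not identify a line, as other lines would match as well, and the line is not named below.

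The deposited table of non-normalized values holds, per the file headers, a signal intensity and a detection p-value for each of 47296 probes on each array. The steps of the deposited detection p-value correspond to 770 negative controls. A second table of the authors holds normalized values on a log2 scale, with the method not given in the sources used here. Its sorted values differed between arrays by a median of 0.0016, as after quantile normalization, and its low values lay about 100.4 intensity units below the quantile means of the signals, as after subtraction of a constant. The series matrix values were identical to that table in all cells (0 differed). The scale of these deposited values is thus log2, with no centring of genes, and the median of each of the 4 columns was 5.58.

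The main values were computed from the signals with limma 3.58.1 in R 4.3.3. The neqc function corrected the background by the normal-exponential model, with the background estimated from the detection p-values, added an offset of 16, quantile-normalized over the 4 arrays and took log2. Differences between arrays are log2 differences of these values, and they understate true changes of dim genes because of the offset. Probes were named through the platform annotation, and their symbols were checked against a reference table by gene identifier, which changed 0 of them. Of the 47296 probes, 30105 had 1 symbol, 8 had several and 17183 were unnamed here. A gene was represented by the probe with the highest mean over the 4 arrays among its probes detected (detection p at most 0.01) on at least 1 array, which gave 12083 genes, 3182 of them with 2 or more detected probes. A gene entered a comparison when its probe was detected on at least 1 of the 2 arrays.

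The comparisons were Nam, Y27632 and Mesoderm against E8, and Nam against Y27632. There are no replicates, so no test was run, no p-value is given, and genes were called by size only, at a difference of at least 2-fold in the normalized values, including genes whose dimmer array did not detect the probe. The number of arrays limits the precision: a difference between 2 arrays cannot be separated from variation between cultures, RNA preparations or hybridisations. As a technical spread, the SD of the log2 difference between probes of one gene was pooled over genes with 2 or more detected probes. It was 0.30 for Nam minus E8, 0.25 for Y27632 minus E8, 0.42 for Mesoderm minus E8 and 0.29 for Nam minus Y27632, and it does not cover differences between cultures. Where the dimmer array did not detect the probe, the fold is a lower bound, taken against the higher of the dim value and the lowest value of a detected probe on that array, and written as at least N-fold. That lowest value was 5.59 on E8, 5.54 on Nam, 5.82 on Y27632 and 5.63 on Mesoderm. Probes detected on Y27632 but not on the other array thus tend to get larger bounds than probes detected only on the other array.

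Before the data were examined, 40 gene lists were fixed, covering pluripotency, germ layers, other cell types a culture could hold, kinase and cytoskeleton pathways, nicotinamide metabolism, stress, metabolism and cell cycle. Of all list members, 47 had no probe in the annotation. For each list the members at least 1.5-fold higher or lower by normalized values were counted, also where the bound was smaller. The median difference was placed among 10000 random lists of the same size drawn from 10 bins of mean expression. A list was said to stand apart when its median fell in the outermost 5% of the random medians, which chance gives for 2 of 40 lists. This percentile describes these arrays and is not a test of the conditions. Some genes are members of more than 1 list, so the lists are not independent and a count of lists can count the same gene repeatedly. The genes named were also fixed by rule: the 12 largest differences in each direction for comparisons with E8, 8 for Nam against Y27632, leaving out uncharacterised symbols, the highest and lowest member and up to 2 more of each list described, and a set of 23 marker and pathway genes. The values of 1 list and of some genes are not reported here.

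For Nam and Y27632, which share the E8 array, 100 sets of 3 unchanged arrays were simulated with the SD of Y27632 minus E8 in each of 10 expression bins as noise, which takes in any effect of Y27632. The calling and list steps were tested on simulated data, 20 sets per comparison with 50 genes changed by each of 4 known folds. With that noise, on the 11390 genes of Nam minus E8, 92.8% of genes changed 2.5-fold and 99.8% of those changed 4-fold were called in the right direction, and 4.3% of those changed 1.5-fold. A shift of 0.5 (log2) planted in 100 lists of 15 genes was found in 100, and 9 of 100 unplanted lists were called. Simulated unchanged genes gave a mean of 47.9 false calls in Nam minus E8, of which 0.05 lay among genes with a log2 level of at least 8 on the brighter array. When the comparison's own spread, from its interquartile range per bin and thus including any real effects, was used as noise instead, these means were 216.7 and 1.85. For Y27632 minus E8, on 10989 genes, the mean was 37.8 false calls, or 22.9 with its own spread, with 0 at a level of at least 8.

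Alternatives changed 1 choice at a time: the authors' normalized table, the series matrix values, no background correction, median scaling without quantile normalization, an offset of 50, a detection p of at most 0.05, detection on both arrays, no detection filter, the mean of a gene's detected probes, and a 1.5-fold threshold. The authors' table and the series matrix hold identical values, yet each counts as an alternative in all numbers below. A filter to genes with a level of at least 8 was added after seeing the data. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome was used here, so no coordinates are reported.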

Results

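Gene expression was measured in human embryonic stem cells under 4 conditions, on 1 Illumina Expression BeadChip array each. Cells in E8, a chemically defined medium that keeps them pluripotent, were the untreated condition, labelled 24 h. Cells in the same medium received nicotinamide, the amide form of vitamin B3, at 10 mM for 24 h (Nam), or the small molecule Y27632 at 10 µM for 24 h (Y27632). A control for differentiation (Mesoderm) received the growth factor BMP4 for 6 days, with no array of untreated cells of that age. The mean signal was 620.5 for E8, 528.5 for Nam, 564.7 for Y27632 and 580.9 for Mesoderm. Of the 47296 probes, 17779 were detected on the E8 array, 18051 on Nam, 16509 on Y27632 and 17541 on Mesoderm, which gave 10840, 10925, 10313 and 10698 named genes. Over all probes, across probes that are not independent replicates, Pearson's r with the E8 array was 0.989 for Nam, 0.992 for Y27632 and 0.953 for Mesoderm. There were no replicates, so each difference is between single arrays and has no replicate check. Unless a fold is given, differences are on the log2 scale.

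The comparison of Mesoderm with E8 is the control for differentiation. Transcription factors of mesoderm were among the genes furthest above E8: HAND1, a factor of lateral plate and extraembryonic mesoderm, was at least 123-fold higher, EOMES, a factor of the primitive streak, at least 146-fold, and ISL1, found in cardiac progenitors and amnion, at least 69.9-fold. The pluripotency factor SOX2 was at least 100.2-fold lower (SD of 0.69 over 2 probes), NANOG was lower by a difference of -4.50, and POU5F1 (OCT4) by -2.31. Other transcripts far above E8 were APLNR, the apelin receptor (at least 86.2-fold), TFAP2A, a factor of ectoderm and trophoblast (at least 66.1-fold, with its 2 probes differing by an SD of 1.34), ALPK2 (at least 59.0-fold), WLS, which carries WNT proteins to the cell surface (at least 114.7-fold by its brightest probe, with a mean difference of 5.65 over 5 probes and an SD of 0.81), IRX3 (at least 82.3-fold), ANXA1 (at least 56.5-fold), GAD1 (at least 39.98-fold, SD of 0.85 over 3 probes), the scavenger receptor COLEC12 (6.84) and BMP2 (6.01). Far below E8 were SIX6, a factor of the eye field (at least 49.2-fold), SOX21 (at least 35.4-fold), CAMKV (at least 35.0-fold), THBS2 (at least 21.2-fold), CNMD (at least 27.1-fold, SD of 0.51 over 2 probes), LRAT, which makes retinyl esters (at least 21.9-fold), the pluripotency gene UTF1 (at least 21.7-fold), NSG1 (-4.73), SOX3 (-4.64) and VSNL1 (-4.60). LMO3 was at least 32.5-fold lower by its brightest probe, but its 2 probes differed by an SD of 2.77.

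Of 21 genes of lateral plate and cardiac mesoderm with a probe, 15 were measured. By normalized values all 15 were at least 1.5-fold higher on the Mesoderm array (median 2.62), MEIS2 (at least 24.1-fold) and TCF21 (at least 1.97-fold) among them. Of 9 primitive streak genes 7 were higher (median 4.23). Among these, TBXT (brachyury) was at least 9.30-fold higher, although its 2 probes differed by an SD of 2.03, MIXL1 at least 2.90-fold, and LHX1 at least 18.9-fold, while FOXH1 differed by 0.10. BMP targets were higher in 12 of 14 cases (median 2.42), with ID1, an inhibitor of differentiation factors, at 2.03 (SD of 0.80 between 2 probes), MSX1 at 5.44, and SMAD7, which inhibits the pathway, at -0.46. The definitive and visceral endoderm list was higher in 9 of 11 genes (median 3.42), including SOX17 (at least 21.3-fold) and FOXA2 (at least 22.7-fold), with HHEX at -0.96. All 9 measured amnion-associated genes were higher (median 2.71), including IGFBP3 at 5.22. Each of these 5 medians lay above all 10000 random lists. Of the mesoderm, endoderm and amnion lists, only 2, 3 and 4 members were measured in Y27632 minus E8. Most members thus entered here because the Mesoderm array detected them, which by itself favours higher values and high ranks. With genes not detected in E8 set at their bounds, the medians were 2.39 for mesoderm, 3.22 for primitive streak, 2.01 for BMP targets, 2.39 for endoderm and 2.51 for amnion. The trophoblast list was higher in 7 of 9 measured genes, at percentile 97.7, with GATA3 at least 1.97-fold higher, SLC40A1 at least 3.17-fold higher and TFAP2C at -1.63. CGA, a hormone subunit made by trophoblast, and CDX2 were not detected on any array.

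Structural and signalling lists also differed between the Mesoderm and E8 arrays. The fibroblast and smooth muscle list was higher in 13 of 15 genes (median 2.01), with ACTA2 at least 12.5-fold higher, LUM at least 7.23-fold higher and THY1 at -2.97. The list of actin cytoskeleton genes and targets of the transcription factor SRF had 13 of 27 genes higher (median 0.47, percentile 99.9), with ACTC1 at 5.14, TAGLN at 3.20 and PDLIM5 at least 1.29-fold lower. Targets of YAP, a co-activator that responds to cell tension, were higher in 14 of 18 genes (median 2.17), with CCN1 at 3.69, CCN2 at 3.44 and AMOTL2 at -0.66. Genes of the epithelial to mesenchymal transition were higher in 8 of 10 genes (median 2.30), including SNAI2 (at least 10.99-fold) and TWIST1 (at least 6.30-fold), and S100A4 stood at 0.10. WNT targets were higher in 7 of 12 genes (median 1.46), with DKK4 at least 14-fold higher and AXIN2 at -1.47, and their median was 0.55 with dim genes at their bounds. The endothelial list (median 1.46, 3 of 4 genes higher, VWF at 3.64, TEK at 0.31) and the basement membrane and integrin list (median 0.44, 6 of 14 higher, ITGA5 at 3.87, ITGA6 at -2.30) stood apart as well. In the other direction, 23 of 26 core and primed pluripotency genes were lower (median -2.09), with LIN28B highest at 0.31. The eye field list was lower in 3 of 4 genes (median -1.45), with OTX2, which is also active in anterior endoderm, at 1.69.

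In all, 1235 genes were at least 2-fold higher and 1330 at least 2-fold lower among 11649 compared, against a mean of 58.1 false calls in simulated unchanged arrays; with the comparison's own spread as noise, which takes in the real changes, it was 2036.7. Of the 40 lists, 16 stood apart as higher and 7 as lower, where chance gives 2. Some of them share members, HAND1 and ISL1 being in both the mesoderm and the amnion list. Of these 23 lists, 17 stood apart under each of the 10 alternatives; with detection required on both arrays, which leaves out genes not detected in E8, the counts were 792 and 830, the primitive streak list did not stand apart, and the medians of the trophoblast (-0.29), endoderm (-0.31) and WNT target (-0.05) lists were below 0. The eye field median was 0.02 with no detection filter, the trophoblast list also lost its place with median scaling and at a level of at least 8, the endothelial list did so with no filter and at that level, and the counts without background correction were 572 and 509.

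**Figure D1:**
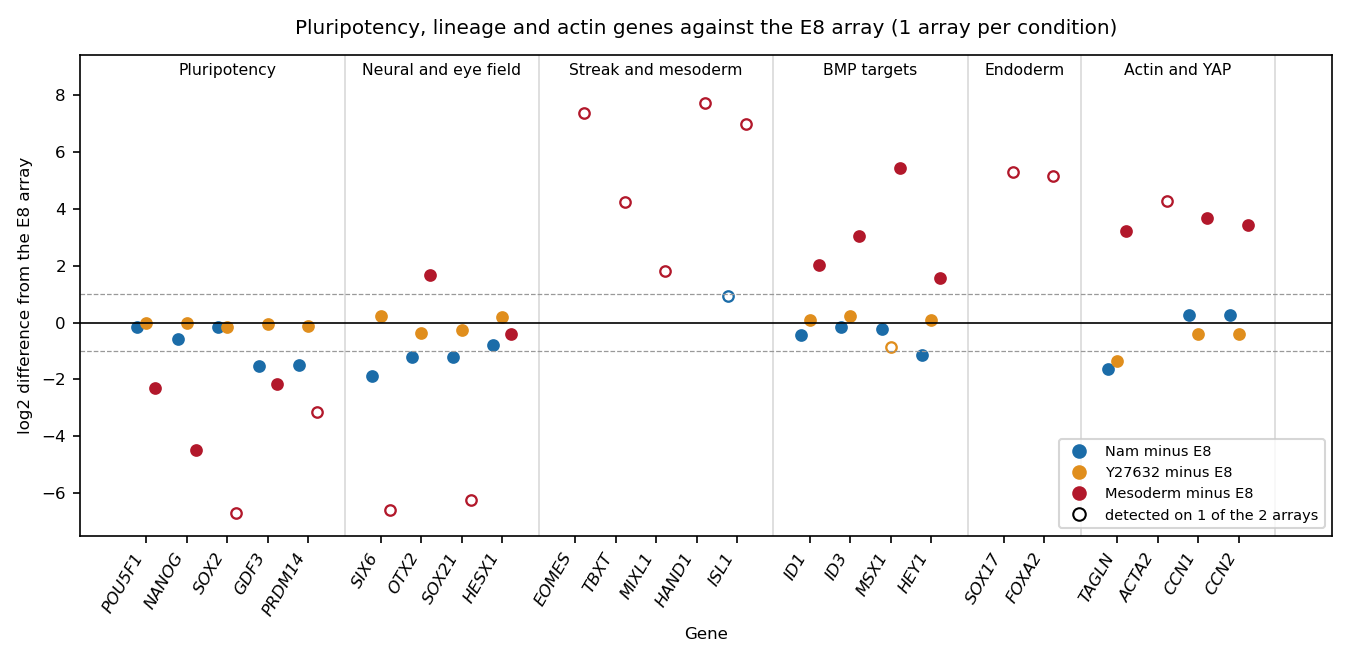
Log2 differences of named pluripotency, lineage, BMP and cytoskeleton genes between each treated array and the E8 array, 1 point per gene and array. Open points mark genes that 1 of the 2 arrays did not detect, and genes that neither array detected have no point. SOX2, NANOG and POU5F1 lie far below 0 on the Mesoderm array and near 0 on the Nam and Y27632 arrays, with NANOG at -0.58 on Nam.

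The comparison of Nam with E8 concerns 24 h of nicotinamide in cells kept in the same medium. Differences were smaller than between Mesoderm and E8. Among the lowest were IDO1, the enzyme that starts tryptophan breakdown (at least 3.89-fold lower, with its 2 probes within an SD of 0.12), SORBS2, an adaptor of actin fibres (-1.99, 2 probes within an SD of 0.03), SIX6 (-1.89), SULF1, which edits heparan sulfate (-1.85), and DPPA5, a gene of pluripotent cells (at least 1.78-fold). POU5F1 differed by -0.14, less than the between-probe SD of 0.30. SOX2 differed by -0.15 for its brighter probe and -0.38 for the mean of its 2 probes (SD 0.32), and NANOG by -0.58, with 2 probes within an SD of 0.08. The early differentiation genes TBXT, MIXL1, HAND1, GATA3 and SOX17 were not detected on the E8 or the Nam array. Of 2 probes of the neural factor PAX6, the brighter was not detected on either, and the other was detected on E8 and was lower and not detected on Nam.

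The remaining genes with the most negative differences were CFAP95 (-2.12), OLIG3, a factor of neural progenitors (at least 2.34-fold lower), FCF1 and NUP43, needed for ribosome assembly and the nuclear pore (-2.00 and -1.92), GINS4 of the replicative helicase (-1.87), BPNT1 (at least 2.85-fold) and GNB4, a G protein subunit (-1.66). The gene furthest above E8 was RNA18SN5, the 18S ribosomal RNA (2.82), whose probe was also higher on the Mesoderm array (2.71). It was followed by the histone gene H4C8 (1.68), PPID, a cyclophilin (at least 2.24-fold higher), SNHG12, a host gene of small nucleolar RNAs (1.56), ACSM5 (at least 1.85-fold), CYCSP52 (at least 1.40-fold), the zinc finger genes ZNF800 (1.45) and ZNF121 (1.34), AP1AR (1.44, with 2 probes differing by an SD of 0.83), the chemokine receptor CCR9 (at least 1.57-fold), the noncoding RNA EGOT (at least 1.35-fold) and DNER, a ligand of the Notch pathway (1.35).

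Of the 40 lists, 8 stood apart as lower on the Nam array than on the E8 array and 0 as higher. Some of the 8 share members: OTX2 is in both the neuroectoderm and eye field lists, and TAGLN in both the fibroblast and SRF lists. The core and primed pluripotency list had a median of -0.21, below all 10000 random lists, although only 2 of its 26 genes were at least 1.5-fold lower: GDF3, a ligand of the Nodal family (-1.54), and PRDM14, a repressor of differentiation genes (-1.50). LIN28B was highest at 0.09. Neuroectoderm genes were lower in 4 of 7 cases (median -0.62, percentile 0.17), with OTX2 at -1.22, SOX21 at -1.20 and DCX at least 1.15-fold higher, and eye field genes in 3 of 4 (median -0.99, percentile 0.01), with PMEL at -0.77 and SIX3 at -0.56. BMP targets had a median of -0.20 (percentile 1.72), with 1 of 9 genes lower, HEY1 (-1.16), while ID1 stood at -0.43 and SMAD9 at 0.28. The fibroblast and smooth muscle list was lower in 5 of 10 genes (median -0.45), with TAGLN, an actin-binding protein of smooth muscle, at -1.64, COL1A2 at -0.96 and COL1A1 at 0.09. SRF and actin genes had a median of -0.09 (percentile 1.93), with 4 of 23 lower, among them ACTG2 (at least 1.21-fold) and ACTA1 (-0.83), and ACTC1 at 0.31. Hypoxia and glycolysis genes were lower in 2 of 24 cases (median -0.32), with NDRG1, induced by low oxygen, at -0.88, ANKRD37 at -0.60 and VEGFA at 0.28, and metallothioneins, which bind zinc and copper, in 2 of 6 (median -0.55), with MT1X at -0.85, MT1H at -0.64 and MT1F at -0.20.

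Lists tied to the action of nicotinamide did not stand apart. The methionine and folate cycle, which supplies methyl groups, lay at percentile 96.5 (median 0.17, 13 of 14 genes above 0). In the list of NAD and nicotinamide metabolism 0 of 18 genes differed by 1.5-fold (median 0.07, percentile 56.9): NAMPT, the enzyme that recycles nicotinamide to NAD, differed by 0.00 (mean of 2 probes -0.13, SD 0.19), NNT by -0.42 and NMNAT3 by 0.51, and NNMT, which methylates nicotinamide, was not detected on any array. The 5 casein kinase 1 genes had a median of -0.01, with CSNK1A1 at 0.02, CSNK1D at -0.15 and CSNK1G2 at 0.33. Apoptosis genes had a median of -0.08 with 1 of 17 lower, BMF (-0.66), and BAD highest at 0.43. The YAP target list, at percentile 95.4, had CCN1 at 0.25, CCN2 at 0.27 (mean of 2 probes 0.07, SD 0.29), IGFBP3 at 1.08, AXL at -0.84 and RBMS3 at least 1.12-fold lower. CDKN1A, the cell cycle inhibitor p21, differed by -0.97, while GAPDH and ACTB differed by -0.14 and -0.07 (means of 3 probes -0.24 and -0.13). Markers of other cell types that did not stand apart were those of mesoderm (3 genes measured), primitive streak (4), trophoblast (4), amnion (5), endoderm (2), neural crest (6), endothelium (4), blood (1) and epithelial keratins and junctions (6).

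In all, 79 genes were at least 2-fold higher and 178 at least 2-fold lower among 11390 compared, and for 54 and 72 of these the dimmer array did not detect the probe. Simulated unchanged arrays gave a mean of 47.9 false calls, and 216.7 with the comparison's own spread as noise, so that many of the calls near background are of a size that noise can give. At a level of at least 8, 7 genes were higher and 71 lower. False calls at that level, both directions together, had a mean of 0.05, and of 1.85 with the comparison's own spread as noise. Median scaling in place of quantile normalization gave 136 higher and 154 lower, no background correction 2 and 32, an offset of 50 gave 10 and 61, and the values normalized by the authors 36 and 106. Of the 8 lists, core pluripotency, fibroblast and smooth muscle, hypoxia and glycolysis and metallothioneins stood apart under each of the 10 alternatives, neuroectoderm and eye field under all except no detection filter, SRF and actin under 8, and BMP targets under 4.

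The comparison of Y27632 with E8 shows the array of cells treated with a small molecule used to keep dissociated stem cells alive. TAGLN was lower by -1.35, with its 2 probes within an SD of 0.10, and CD55, which shields cells from complement, was higher by 1.33 (2.51-fold). POU5F1 and NANOG differed by 0.00 and 0.00, SOX2 by -0.14 for its brighter probe and -0.33 for the mean of 2 (SD 0.26), and CCN1 and CCN2 by -0.40 and -0.41. Most other large differences lay near background: PGF, a growth factor of the placenta, was at least 1.69-fold higher, ADAM12 at least 1.29-fold, LRRC36 at least 1.28-fold, EGOT at least 1.28-fold, ITSN2 at least 1.34-fold, LINC01538 at least 1.28-fold, SOST, a WNT antagonist, at least 1.41-fold, the tight junction gene CLDN4 at least 1.90-fold, KDM4D, a histone demethylase, at least 2.20-fold, PM20D1 at least 1.45-fold and SNORD4B at least 1.27-fold. GINS4 (-1.11) and JDP2 (-1.08) were lower. Bounds for the other low genes were at least 1.19-fold for SERPINA11, 1.17-fold for SNORA59B, 1.42-fold for GJC3, 1.04-fold for SLC35E4, 1.01-fold for CELF2-AS2, 1.59-fold for TEX14, 1.19-fold for PDE6B and 1.18-fold for MNX1, and no fold can be given for SLFN14. Bounds of higher and lower genes cannot be compared, since the lowest value of a detected probe was 5.82 on Y27632 and 5.59 on E8.

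Of the 40 lists, 3 stood apart as higher on the Y27632 array and 2 as lower, and their shifts were small. FGF and ERK targets had a median of 0.18, above all 10000 random lists, with DUSP5 at 0.47, DUSP6, a phosphatase that limits ERK, at 0.39, and PHLDA1 at -0.28, and 0 of 11 reached 1.5-fold. Heat shock genes had a median of 0.13 (percentile 99.6), with HSPE1 at 0.36. BMP targets had a median of 0.14 (percentile 98.5), with SMAD9 at 0.29, ID1 at 0.07 and MSX1 at least 1.63-fold lower. SRF and actin genes had a median of -0.09 (percentile 0.29), with 3 of 23 lower by normalized values. These were TAGLN, MYL9, the myosin light chain (at least 1.23-fold), and ACTG2, for which no fold can be given. Only TAGLN is established as at least 1.5-fold lower. ZYX was at 0.17, and the median with dim genes at their bounds was -0.04. Neuroectoderm genes had a median of -0.26 (percentile 2.01), with ZIC1 at least 1.19-fold lower and PAX6 at least 1.19-fold higher by its brighter probe, although its 2 probes differed by an SD of 0.76 and their mean difference was 0.05. Core pluripotency genes had a median of -0.02, with TERT at -0.38 and DPPA4 at 0.10. The casein kinase 1 list was at -0.07 (CSNK1A1 at -0.25), YAP targets at 0.01, apoptosis genes at 0.00 and NAD metabolism genes at -0.04 (NAMPT at -0.13, mean of 2 probes 0.02). CDKN1A differed by 0.10, GAPDH by -0.02 and ACTB by -0.09 (means of 3 probes -0.09 for GAPDH and -0.11 for ACTB), and TBXT, MIXL1, HAND1, GATA3, SOX17 and ACTA2 were not detected on the E8 or the Y27632 array.

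In all, 25 genes were at least 2-fold higher and 20 at least 2-fold lower among 10989, while the simulation of unchanged arrays, whose noise was taken from this same comparison, gave a mean of 37.8 calls, and 22.9 when that noise was taken from its interquartile range. Median scaling gave 44 higher and 10 lower and an SRF and actin median of 0.01, and the neuroectoderm median was 0.00 with a detection p of at most 0.05 and 0.04 with no detection filter. The FGF and ERK and heat shock lists stood apart under each of the 10 alternatives, and the other 3 lists under 7 each; at a level of at least 8, where 18 SRF and actin genes were measured, that list lay at percentile 15.1.

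**Figure D2:**
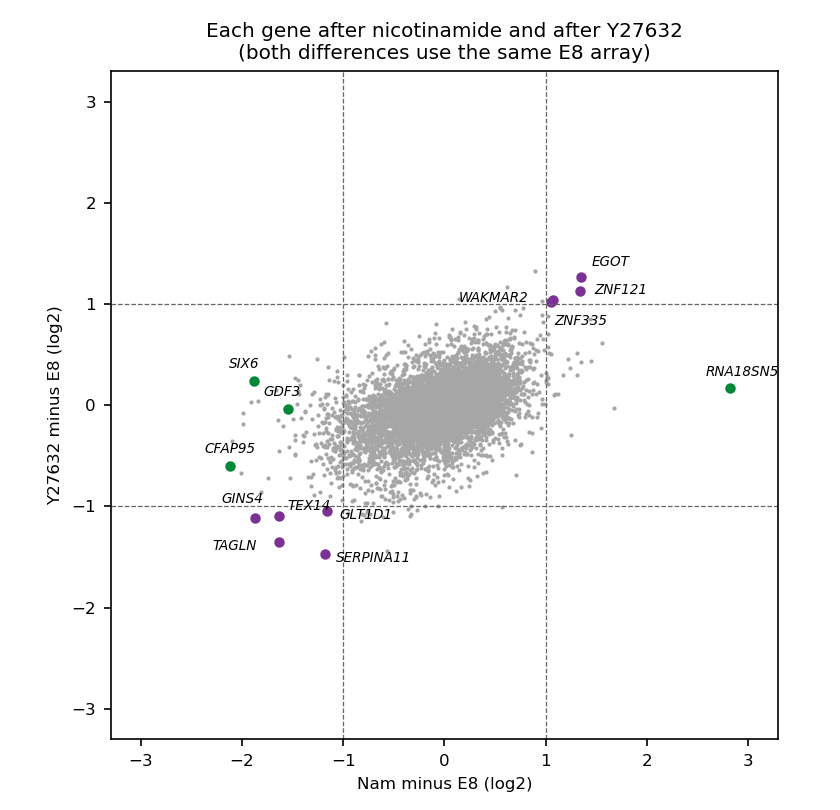
Log2 difference of each gene between Nam and E8 (x axis) and between Y27632 and E8 (y axis), with the genes at least 2-fold apart from E8 in the same direction on both arrays, by normalized values, named in purple and 4 genes of the Nam comparison in green. Both axes share the E8 array, which by itself tilts the cloud. In purple, 4 genes are higher and 5 lower on both arrays.

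Nam and Y27632 were set against each other to ask how far the response to nicotinamide resembles that to Y27632. The E8 array is part of both differences from E8, so that the same noise enters both. Genes called as lower in both by their normalized values were the actin-binding gene TAGLN, GINS4, TEX14, GLT1D1 and SERPINA11, and genes called as higher in both were EGOT, WAKMAR2, ZNF121 and ZNF335. Only for TAGLN, GINS4 and ZNF121 did all 3 arrays detect the probe, and the bounds of the other 6 genes lay below 2-fold. The 5 shared lower genes compare with a mean of 2.41 and a maximum of 6 in simulated unchanged arrays with a shared control, and with 0.33 for independent lists. The 4 shared higher genes compare with 2.35 (maximum 7) and 0.02. Across 11477 genes, which are not independent replicates, the differences from E8 had an r of 0.43 and a rank correlation of 0.41, against 0.50 and 0.47 in the simulation. The simulation gave both differences the same spread, whereas the observed SD was 0.38 for Nam minus E8 and 0.24 for Y27632 minus E8. Its correlations and overlaps are thus not matched to the Nam array, and the lower observed correlation decides nothing. The covariance of the observed differences, 0.0403, lay above the simulated mean of 0.0304 and above the highest simulated value, 0.0328. The simulated value is set by giving the E8 and Y27632 arrays equal noise. An E8 array with a larger share of that noise would raise the covariance without any shared response, so the covariance decides nothing either. With 1 control array the control could not be split, and part of these overlaps may come from it. With the values normalized by the authors, 2 genes were shared as higher and 2 as lower.

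The direct difference between Nam and Y27632 does not use the E8 array. SIX6 (-2.13), CYP1B1, an enzyme of steroid and xenobiotic metabolism (at least 2.78-fold), NUP43 (-1.95), SORBS2 (-1.91), SULF1 (-1.89), FCF1 (-1.81, SD of 0.49 over 2 probes), GNB4 (-1.81, SD of 0.45 over 2 probes) and IDO1 (at least 3.04-fold) were lowest in Nam. RNA18SN5 (2.66), H4C8 (at least 2.87-fold), PPID (at least 1.90-fold), VAPB (at least 2.59-fold), the histone gene H2BC5 (1.54), the receptor kinase ALK (at least 1.49-fold), SCARNA27 (at least 1.13-fold) and VAT1L (at least 1.45-fold) were highest. NANOG was lower in Nam than in Y27632 by -0.57, POU5F1 by -0.14 and CDKN1A by -1.07, SOX2 differed by -0.01, and CCN1 and CCN2 were higher by 0.65 and 0.68 (mean of 2 CCN2 probes 0.48). CSNK1A1 differed by 0.28 with an SD between its 3 probes of 0.27, NAMPT by 0.13 (mean of 2 probes -0.15, SD 0.40), GAPDH by -0.11 (mean of 3 probes -0.15), ACTB by 0.02 (mean of 3 probes -0.02) and ID1 by -0.50, and PAX6 was at least 1.23-fold lower.

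Of the 40 lists, 13 stood apart as lower in Nam than in Y27632 and 1 as higher. For each, the count at least 1.5-fold apart is followed by the lowest and the highest member by normalized values. The rank of a member given as at least N-fold or without a fold is not established, since 1 array did not detect it. Core pluripotency had a median of -0.13, with 2 of 26 genes lower (GDF3 at -1.51, PODXL at 0.25), naive pluripotency -0.53, with 2 of 5 lower and 1 higher (KLF4 at -0.75, TFCP2L1 at least 1.51-fold higher). Neuroectoderm had a median of -0.62, with 4 of 8 lower and 1 higher (PAX6, HESX1 at -0.99, ZIC1 at least 1.1-fold higher), eye field -0.84, with 4 of 5 lower (SIX6, SIX3 at -0.58), and endoderm -0.65, with 2 of 3 lower (CER1 at least 1.36-fold, HHEX at -0.65, FOXA3 at -0.56). BMP targets were at -0.34, with 1 of 9 lower and 1 higher (HEY1 at -1.25, MSX1 at least 1.38-fold higher), and FGF and ERK targets at -0.21, with 3 of 11 lower (ETV1 at least 1.45-fold, DUSP5 at -0.73, SPRED2 at 0.17). Fibroblast and smooth muscle genes had a median of -0.25, with 2 of 10 lower (COL1A2 at -0.88, and COL6A3, for which no fold can be given), basement membrane and integrins -0.16, with 1 of 14 lower (COL4A2 at -0.72, LAMA5 at 0.26). Hypoxia and glycolysis had a median of -0.33, with 1 of 24 lower (NDRG1 at -0.98, VEGFA at 0.16), and metallothioneins -0.68, with 4 of 6 lower (MT1E at -1.08, MT1F at -0.38). Targets of p53 were at -0.24, with 5 of 19 lower and 1 higher (GDF15 at least 1.45-fold lower, and POLH, for which no fold can be given), and endoplasmic reticulum chaperones at -0.13, with 0 of 13 apart (EDEM1 at -0.49, DNAJB11 at 0.34). The methionine and folate cycle, which supplies methyl groups, was higher (median 0.20, percentile 99.9), with 0 of 14 apart (MTR at -0.12, MAT2A at 0.43). With dim genes at their bounds the medians of neuroectoderm, eye field and endoderm were -0.34, -0.60 and -0.56. SRF and actin genes did not stand apart (median -0.02, percentile 20.1). In all, 71 genes were at least 2-fold higher in Nam than in Y27632 and 120 lower among 11173, against a mean of 43.1 false calls in simulated unchanged arrays and 124.05 with the comparison's own spread as noise. At a level of at least 8, 4 genes were higher and 31 lower. False calls at that level, both directions together, had a mean of 0, and of 0.45 with the comparison's own spread as noise. With the values normalized by the authors, over all levels, the counts were 26 and 64. Of the 14 lists, 9 stood apart under each alternative that gave a value, and naive pluripotency, eye field and FGF and ERK targets lost their place under 1, endoderm under 2 and endoplasmic reticulum chaperones under 3.

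**Figure D3:**
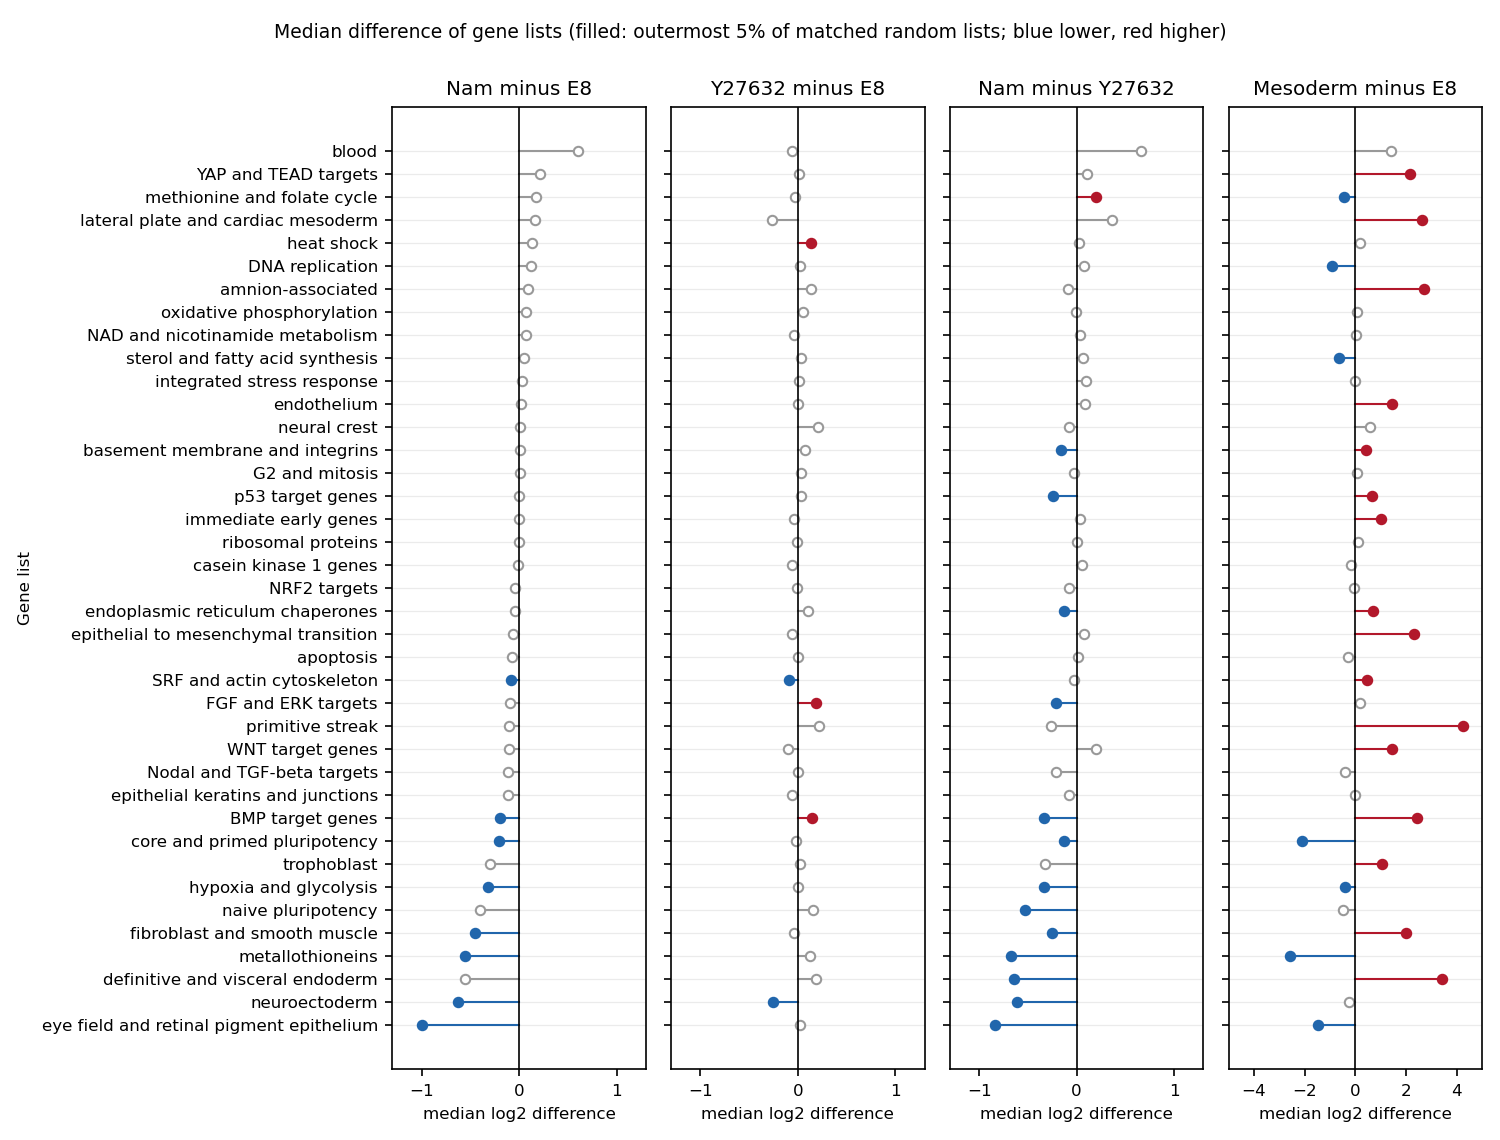
Median log2 difference of gene lists in Mesoderm, Nam and Y27632 against E8, and in Nam against Y27632, with a wider axis for Mesoderm. Filled points stood apart from matched random lists, in red as higher and in blue as lower, and the Mesoderm panel holds 16 red and 7 blue points, the Nam minus E8 panel 0 and 8.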

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

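Probes that the platform annotation leaves unnamed were outside all gene comparisons, and they were looked at only after the results for named genes were known. Of 4180 such probes detected on the Nam or the E8 array, 82 were at least 2-fold higher on the Nam array than on the E8 array, the untreated control, and 75 were at least 2-fold lower. On the Y27632 array 28 of 3749 were higher and 31 lower, and on the Mesoderm array 315 of 4165 were higher and 367 lower. The furthest single probes differed by 1.78 and -2.13 on the Nam array, by 1.52 and -1.55 on the Y27632 array and by 5.92 and -5.02 on the Mesoderm array. No explanation was tested, because these probes carry no gene name here.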

How the results depend on the processing

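The filter to genes with a log2 level of at least 8 was chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each condition has 1 array, and no array could be left out for the same reason. Of 1344 values of named genes under the alternatives, 1062 moved by less than the spread between probes, 281 moved by more and 1 reversed. Of 1583 list medians, 1399 moved by less than the SD of random lists, 177 by more and 7 reversed. A change of sign was counted as reversed only for genes at least 2-fold apart and lists that stood apart in the main values. Changes of sign in all other genes and lists are within the other counts. Of 108 counts of genes, 39 stayed within 1.5 times the main count. Dim signal limits these counts: the dimmer array did not detect 126 of the genes called in Nam against E8, 38 in Y27632, 943 in Mesoderm and 131 in Nam against Y27632, and a constant added or subtracted before log2 acts most on such genes. Beyond what the construction of an alternative shows, the cause was not tested.

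Counts of genes at least 2-fold higher and lower are given in that order. With the authors' normalized table, and identically with the series matrix values, the counts were 36 and 106 for Nam against E8, 8 and 7 for Y27632 against E8, 26 and 64 for Nam against Y27632, and 2 and 2 for genes shared by Nam and Y27632. With no background correction they were 2 and 32 for Nam, 0 and 1 for Y27632, 572 and 509 for Mesoderm, 1 and 16 for Nam against Y27632, and 0 and 1 shared, and the correlation of the Nam and Y27632 differences was 0.479, that of Nam minus Y27632 with Mesoderm minus E8 0.111. Median scaling without quantile normalization gave 136 higher for Nam, 44 and 10 for Y27632, 7 shared higher and a correlation of 0.473. An offset of 50 gave 10 and 61 for Nam, 0 and 1 for Y27632, 861 lower for Mesoderm, 6 and 30 for Nam against Y27632, 0 and 1 shared, and a correlation of 0.452. A detection p of at most 0.05 gave 46 higher for Y27632 and a correlation of 0.407. Genes detected on both arrays gave 25 and 106 for Nam, 3 and 4 for Y27632, 792 and 830 for Mesoderm, 9 and 51 for Nam against Y27632, 1 and 2 shared, and a correlation of 0.469. With no detection filter there were 46 higher for Y27632, and the correlation of Nam minus Y27632 with Mesoderm minus E8 was 0.0697. A 1.5-fold threshold gave 562 and 762 for Nam, 174 and 223 for Y27632, 2361 and 2621 for Mesoderm, and 524 and 546 for Nam against Y27632. A level of at least 8 gave 7 and 71 for Nam, 1 and 2 for Y27632, 727 and 691 for Mesoderm, 4 and 31 for Nam against Y27632, 1 and 2 shared, and a correlation of 0.508.

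The reversed values were these. In Y27632 against E8 the neuroectoderm median was 0.0048 with a detection p of at most 0.05 and 0.043 with no detection filter, the SRF and actin median was 0.012 with median scaling, and SERPINA11 stood at 0.0015 with no detection filter, where another, undetected probe is its brightest. In Mesoderm against E8 the trophoblast median was -0.29, the endoderm median -0.31 and the WNT target median -0.054 among genes detected on both arrays, which leaves out the members not detected in E8, and the eye field median was 0.025 with no detection filter, which adds undetected members.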

Other observations

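The 40 lists were fixed before the data were examined, while the tests of explanations and the histone class were chosen only after the results were seen. On the Mesoderm array, lists of stress and metabolism differed from E8 as well. Targets of p53 were at least 1.5-fold higher in 12 of 20 genes (median 0.68), with GDF15, a stress-induced cytokine, at least 36.7-fold higher, CDKN1A at 3.74 and ZMAT3 at -0.90. Endoplasmic reticulum chaperones were higher in 10 of 13 genes (median 0.69), with DNAJB9 at 1.61 and HSPA5 at 1.06, and immediate early genes in 8 of 11 (median 1.03), with EGR1 at 2.17 and MYC at -0.70. Genes of DNA replication were lower in 10 of 14 cases (median -0.91), with RRM2, which makes deoxynucleotides, at -1.90 and TYMS at 0.99, whereas the G2 and mitosis list had a median of 0.06. Sterol and fatty acid synthesis was lower in 12 of 22 genes (median -0.64), with LSS at -1.61 and SC5D at 0.73, and hypoxia and glycolysis in 11 of 24 (median -0.41), with the hexokinase HK2 at -2.60 and MXI1 at 1.14. All 6 metallothioneins measured were lower (median -2.59), with MT1X at -3.82, and the methionine and folate cycle had a median of -0.46, with MAT2A at -1.27.

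On the Nam array, p53 targets had a median of 0.00, with DDB2 at -1.05 and MDM2 at least 1.23-fold higher, and did not stand apart. The integrated stress response had a median of 0.03, with DDIT4 at -1.18 and ATF5 at 0.65. DNA replication (0.12), G2 and mitosis (0.01), ribosomal proteins (-0.01), oxidative phosphorylation (0.07), sterol and fatty acid synthesis (0.05) and NRF2 targets (-0.04) did not stand apart either. Of 21 clustered histone genes, 4 were at least 1.5-fold higher and 1 lower than in E8 (median 0.26, percentile 98.5), with H4C8 at 1.68 and H2BC9 at -0.82, while in Nam against Y27632 the class lay at percentile 89.3.

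The probe for 18S ribosomal RNA was higher than in E8 by 2.82 on the Nam array and 2.71 on the Mesoderm array, against 0.17 on Y27632. If more RNA without a poly(A) tail had been labelled on the Nam array, probes of 28S, 7SK, 7SL, U6 and RNase P RNA should be higher too. The median of 7 such probes was 0.105 with an SD of 0.27, far below 1.41, the bound set at 50% of the 18S difference. Over 9 probes, which adds dim ones of U6atac, it was 0.13. The clustered histone genes, whose messenger RNAs also lack a tail, were higher (median 0.26, percentile 98.5, 4 of 21 at least 1.5-fold higher and 1 lower). Their median lay below the bound too, but H4C8 at 1.68 lay above it, so a smaller or uneven gain is not excluded. An equal rise of labelled 18S and 28S RNA, which are cut from the same precursor, is argued against on the Nam array. There, the higher 28S probe differed by 0.51. These probes read only what was labelled of an RNA without a tail. How much ribosomal RNA the Nam cells held thus stays undecided. On the Mesoderm array the same median was 0.598 over 7 probes (SD 0.76) and 0.97 over 9, and since the outcome depended on which probes were counted, labelling of RNA without a tail cannot be told apart from other causes there. What raised the single 18S probe on the Nam array stays open and could include the probe itself or uneven priming of 18S RNA, neither of which was tested.

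The hypoxia and glycolysis, metallothionein and core pluripotency lists were lower on the Nam array than on the E8 array. A deviating E8 array is argued against, since all 3 lists were also lower against Y27632, at percentile 0.26 or below. Under 4 other normalizations, backgrounds or offsets the highest percentile was 0.02. Of these, only median scaling is known to leave out quantile normalization, so the argument against that step rests on it. Both checks were chosen after the results were seen. A move of the Nam cells along the path of the Mesoderm cells would lower the genes that are lower in Mesoderm, and the 1277 of these that were measured in both comparisons, which include members of the 3 lists, lay at percentile 0 in Nam against Y27632, with a median of -0.12, 159 of them at least 1.5-fold lower and 23 higher. It would also raise the genes that are higher in Mesoderm. The 827 of the 1235 such genes that were detected on the Nam or the Y27632 array lay at percentile 1.3, on the lower side. Of these, 62 were at least 1.5-fold higher and 79 lower, and their median was 0.00, against 0.02 for random lists. As a set they thus stood apart on the side opposite to such a move, by a small amount. The SD of 0.46 between single genes does not measure the spread of that median. The rest of the 1235 were detected on neither array, HAND1 and EOMES among them. The percentile of 1.3 thus leaves out genes that did not rise to detection on Nam. Genes lower in Mesoderm went with such a move and the measured genes higher in Mesoderm did not, so that such a move cannot be told apart from other causes. An effect of nicotinamide and differences between single cultures, such as density or medium age, stay open and were not tested, since each condition has 1 array.

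The SRF and actin list was lower on both the Nam and the Y27632 array than on E8. Against each other, Nam and Y27632 placed it at percentile 20.1, which would follow from a deviating E8 array and equally from a like response to both compounds, so that these cannot be told apart with 1 shared control. On the Y27632 array the list also lost its place with median scaling, where its median was 0.01. There, the 18 genes with a level of at least 8 lay at percentile 15.1 with a median of -0.01. Dim members and the normalization thus stay open as sources of the shift. On the Nam array the 18 genes at that level lay at percentile 2.54, next to the bound of the outermost 5%, which decides nothing, and the margin for an undecided outcome was set after this value was seen. TAGLN, at a level of 9.3 in E8 and with 2 probes, was lower on both arrays (-1.64 and -1.35), which a deviating E8 array would give as well.

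Genes that differed between Nam and Y27632 overlapped with those that differed between Mesoderm and E8, comparisons that share no array. Among the 10739 genes measured in both comparisons, 102 were at least 2-fold lower in Nam than in Y27632; of these, 43 were also lower in Mesoderm than in E8, against 12.1 for independent lists, and 26 were higher, against 7.85. Of the 35 that were higher in Nam, 13 were higher in Mesoderm, against 2.70, and 1 was lower, against 4.16. The figures for independent lists take no account of expression level, and 131 genes called in Nam against Y27632 were not detected on the dimmer array. Genes lower in Nam exceeded them in both directions of Mesoderm. The overlaps are thus not set against a matched chance level. Over 12083 genes, which are not independent replicates, the 2 differences had an r of 0.086 and a rho of 0.083.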
